A study of Mus musculus with 4 samples.

How the data were processed

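Total RNA from mandibular molar tooth germs of ICR mouse embryos (an outbred laboratory strain) was profiled at 4 stages, embryonic days 11, 12, 14 and 16 (E11, E12, E14 and E16), with 1 Agilent microRNA array per stage. Per the labels' protocols, 100 ng of total RNA was dephosphorylated, ligated to pCp-Cy3 and hybridised with the Agilent miRNA labelling kit, so each array has 1 colour. The sources used here do not state how many embryos were pooled for an array. The number of arrays, 1 per stage, limits the precision: there are no replicates, and no p-value or spread between samples can be given for a difference between stages.

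Per the file headers, the deposited intensity of each feature is the total gene signal, with an error of that signal and a detection flag. The column names are those of Agilent's gene-level output; the software version, array design and background method are not given in the sources used here. Each array reports 718 features, 696 miRNAs and 22 control features, and an undetected feature is written as 0.1. These deposited intensities are not scaled between arrays. The authors' series value table holds intensity on a linear scale as well. All its detected values (209, 221, 249 and 250 per stage) were recovered within 0.1% by quantile normalization of the deposited signals over all features, control features and undetected values included. No centring was found. Its columns have medians of 123, 106, 83.7 and 83.0 over detected values at E11, E12, E14 and E16, and of 0.1 over all values. That table was used only as an alternative. The authors' method for it is not given in the sources used here.

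A miRNA was taken as detected where its flag says so. The lowest ratio of a detected signal to its stated error was 3.01. The median error of a detected signal was 9.04% to 9.55% of the signal, and the highest 32.0% to 33.3%. These errors describe measurement on 1 array and hold nothing of the variation between embryos or litters.

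Control features were left out. The log2 signal of each detected miRNA was taken relative to its array's 75th percentile, computed over the 197 miRNAs detected on all 4 arrays. A difference between stages is later minus earlier on this log2 scale, and its error combines both stated signal errors. A miRNA counted as higher or lower where it was detected at both stages and differed by at least 2-fold; this is a rule of size, not of significance. A miRNA detected at only 1 of the stages compared has a bound ("at least N-fold"), taken against the lowest detected signal of the other array (5.48, 7.43, 5.69 and 6.51 at E11, E12, E14 and E16) after scaling.

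The 75th percentile of the signals was higher by 1.44 on the log2 scale at E16 than at E11, with steps of 0.67, 0.41 and 0.36. Scaling by it places the median of all miRNAs detected at both E11 and E16 at -0.74, against 0.69 in the deposited signals. Differences are therefore read beside this median, and the text gives ranges over the 6 scalings for the 4 miRNAs it opens with; the errors beside other differences are technical and leave the choice of scaling out. The 6 scalings were the main one, the 75th percentile over all probes, the median of the miRNAs detected on all arrays, quantile normalization, no scaling, and the authors' table.

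The comparisons were E16 versus E11, each pair of consecutive stages, and the course over all 4 stages. The stages, lists, size rule and naming rule were fixed before the data were examined. For E16 versus E11 the rule named the 12 largest differences each way, and for each step the 5 largest each way. It also named up to 5 miRNAs each way detected at only 1 of the stages, the 10 brightest miRNAs of each stage, up to 4 members of highest mean level per list, and miR-135a and miR-135b at all stages.

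The lists were epithelium-enriched miRNAs; mesenchyme-enriched miRNAs; the let-7, miR-29, miR-30, miR-34 and miR-449, miR-135 and miR-181 families; the miR-125, miR-99 and miR-100 family; the miR-15, miR-16, miR-195, miR-497 and miR-322 family. They also held the miR-17-92 cluster with its paralogs, the miR-302 and miR-290 clusters, the Dlk1-Dio3 cluster, the Hox cluster miRNAs and the miR-23, miR-27 and miR-24 clusters. Markers of muscle, erythroid, leukocyte, endothelial, neural, sensory ganglion (miR-183 cluster) and cartilage cells were added. For a list with at least 3 members detected at both stages, the median log2 difference was set against 10000 random lists of the same size matched on mean level in 5 bins. The resulting percentile describes these arrays and is no p-value. Both arms of a precursor count as separate miRNAs.

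Probe names were kept as on the arrays. Of the 696 names, 656 matched a miRNA gene in the RefSeq table of assembly GRCm38.p6 and 40 did not, 21 of them detected. That table served only for names and for which genes neighbour each other. Members of a family with nearly identical sequences (let-7, miR-17) can hybridise to each other's probes, and the arrays cannot separate this. The brightest miRNAs and the list members named were chosen by signal. Probes differ in affinity, so this choice gives no order of abundance between miRNAs, and values are compared only between stages of the same probe.

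The size rule was tested on simulated data for E16 versus E11 with 209 miRNAs and known changes. It recovered 10 of 10 miRNAs raised 4-fold, 8 of 10 raised 2.5-fold, 10 of 10 lowered to 0.25 and 10 of 10 lowered to 0.4 of their level. It called 0 of 169 unchanged miRNAs, whose mean was shifted by -0.14. The simulation copied the E11 signals to every stage, with a constant per array and only the stated errors as noise. It held no variation between embryos and no widening of the signals between arrays. On the real arrays the 75th percentile lay 1.58 (log2) above the median at E11 and 2.10 at E16. The 0 of 169 is therefore no rate of false calls for these stages. Alternatives covered the scaling, the set of miRNAs, the fold threshold (1.5-fold and 3-fold), the stated error, the detection rule, the members of lists and the stages left out. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.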

Results

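MicroRNAs were measured in mouse mandibular molar tooth germs at E11, E12, E14 and E16, days over which the molar goes from a thickened dental epithelium through bud and cap to bell stage. Each stage has 1 array. The arrays detected 209, 221, 249 and 250 of 696 miRNAs at E11, E12, E14 and E16, or 30.0%, 31.8%, 35.8% and 35.9%. In all, 197 were detected at every stage and 424 at none. Errors printed with ± are the combined measurement errors of the arrays, not a spread between animals.

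The 10 entries of highest signal at each stage are named without order, since probes differ in affinity and signal does not give relative abundance. miR-125b-5p and the mesenchyme-enriched miR-199a-3p were named at every stage. Their signals were 5164 ± 435 and 5055 ± 366.8 at E11, and 7714 ± 634 and 5760 ± 422 at E16. All signals in this paragraph are as deposited, not scaled between arrays, so they give no change between stages. After scaling, both miRNAs were lower at E16 than at E11. Named at E11 were also miR-214, miR-199b*, miR-19b and miR-92a. E12 added miR-199a-5p and miR-130a, and kept miR-214, miR-199b* and miR-19b. The epithelial miR-205 was named at E14 (3517 ± 254) and E16 (5317 ± 386), and let-7a (3851 ± 284), let-7f (3485 ± 271) and miR-199b* at E16. The remaining entries have no miRNA gene in the RefSeq table: miR-1937b, miR-720 and miR-2141 at every stage, miR-2138 at E11 and E14, miR-2140 at E14 and E16, and miR-2145 and miR-2146 at E14.

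The first comparison, E16 versus E11, asks which miRNAs differ between the start and the end of the series. miR-31 was 28.6-fold higher at E16 (log2 4.84 ± 0.35, 4.81 to 6.28 over the 6 scalings), let-7b 17.4-fold (4.12 ± 0.26, 4.08 to 5.55) and miR-27a 7.27-fold (2.86 ± 0.22, 2.83 to 4.30). At least 2-fold higher were 8 of 9 let-7 family members, 4 of 6 epithelial miRNAs and 3 of 5 members of the miR-23, miR-27 and miR-24 clusters. Of the imprinted Dlk1-Dio3 cluster 23 of 32 members were at least 2-fold lower (3 of 32 on the deposited signals). The Igf2 intronic miR-483 was 12.1-fold lower (-3.60 ± 0.47, -4.09 to -2.16 over the scalings). However, its deposited signals of 32.4, 8.04, 37.2 and 7.24 at E11, E12, E14 and E16 place it among 24 entries, detected on all arrays, that peaked at E14. Of 205 miRNAs detected at both stages, 28 were at least 2-fold higher and 77 at least 2-fold lower at E16, against 44 and 35 with median scaling and 92 and 9 on the deposited signals.

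The remaining 9 of the 12 largest differences upward were miR-22 (2.53 ± 0.34), miR-193b (2.48 ± 0.45), miR-152 (2.43 ± 0.43), miR-200a (2.28 ± 0.23), let-7i (2.24 ± 0.15), let-7c (2.15 ± 0.15), miR-135b (2.02 ± 0.46), miR-203 (1.88 ± 0.18) and miR-365 (1.72 ± 0.21). Their 12 counterparts downward, with miR-483, were miR-543 (-3.34 ± 0.50), miR-130b* (-3.29 ± 0.36), miR-188-5p (-3.10 ± 0.26), miR-483* (-3.09 ± 0.29), miR-409-3p (-2.74 ± 0.27) and miR-433 (-2.53 ± 0.37). They went on with miR-214 (-2.51 ± 0.15), miR-342-3p (-2.45 ± 0.15), miR-369-5p (-2.41 ± 0.40), miR-154* (-2.39 ± 0.26) and miR-376c (-2.33 ± 0.50). Each of these 24 kept its direction under all 6 scalings. Constant shifts could not have turned them, since the largest, 1.44 upward without scaling, is smaller than every fall. The same holds for the differences named for each step, where the shift without scaling is 0.67, 0.41 and 0.36.

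**Figure D1:**
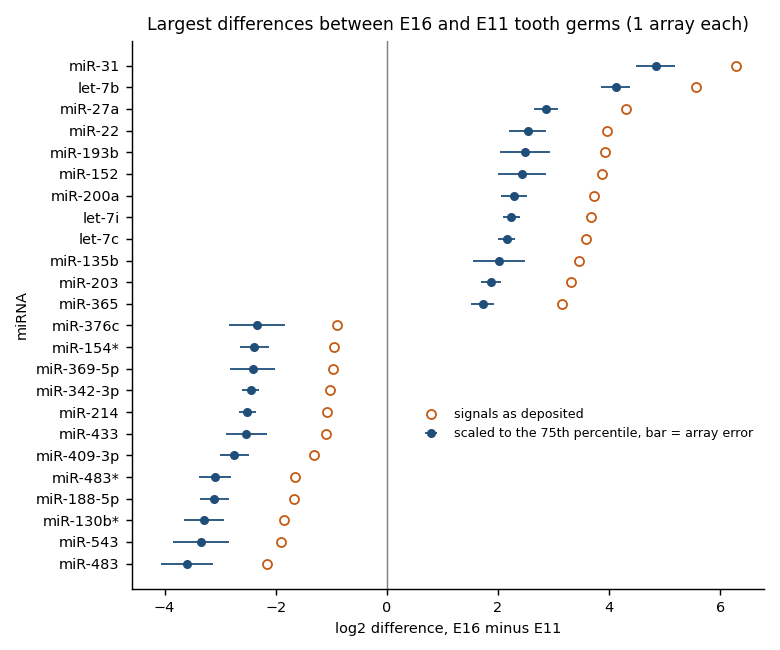
Log2 difference between E16 and E11 (x axis) of the 12 miRNAs with the largest difference each way, 1 array per stage. Filled points are scaled to the 75th percentile with the combined array error as bars, and open points are the signals as deposited; both lie on the same side of 0 for every miRNA, from miR-31 at 4.84 to miR-483 at -3.60.

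At E16 45 miRNAs were detected that were not detected at E11. The 5 of highest level were the epithelial miR-141, at least 29.8-fold higher, miR-31* (at least 29.6-fold), miR-875-5p (26.1), the hypoxia-induced miR-210 (17.9) and the p53 target miR-34a (10.7). In the other direction 4 were detected only at E11: miR-323-3p, at least 17.8-fold lower at E16, miR-409-5p (12.6), miR-18a* (4.27) and miR-135a* (3.12). On the deposited signals those 4 bounds are 6.58, 4.68, 1.58 and 1.15, and the 5 upward bounds 80.5, 80.2, 70.6, 48.5 and 29.1. All these bounds, and those of the steps below, are nominal. A probe with a larger error can be undetected above the array's lowest detected signal.

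Of 9 let-7 family members, a family known to accumulate as embryonic cells differentiate, 8 were at least 2-fold higher at E16 under the main scaling. The family's median was 1.58, at the 100th percentile of random lists. let-7a (1.10 ± 0.15) and let-7f (1.58 ± 0.16) were among them. let-7e was the exception at -0.80 ± 0.15, which turned to 0.64 on the deposited signals. Of 6 epithelial miRNAs, 4 were at least 2-fold higher and none 2-fold lower, with a median of 1.35 (percentile 99.4); all 6 passed on the deposited signals. miR-200c was at 1.44 ± 0.17, miR-429 at 1.25 ± 0.16, miR-205 at 0.66 ± 0.15 and miR-200b at 0.60 ± 0.16. The miR-23, miR-27 and miR-24 clusters had 3 of 5 members higher (5 on the deposited signals) and a median of 1.26 (percentile 98.2), with miR-23a at 1.36 ± 0.16, miR-27b at 1.26 ± 0.17, miR-24 at 0.75 ± 0.15 and miR-23b at 0.24 ± 0.17.

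In the Dlk1-Dio3 cluster 23 of 32 members were at least 2-fold lower and 0 higher, with a median of -1.60 (percentile 0). On the deposited signals 3 were lower, 6 higher, and the median was -0.17, below the all-miRNA median of 0.69. Its members of highest level were miR-494 (-0.26 ± 0.16), miR-127 (-0.90 ± 0.16), miR-329 (-2.03 ± 0.17) and miR-434-3p (-1.55 ± 0.17); the first 2 turned positive on the deposited signals. The proliferation-associated miR-17-92 cluster and its paralogs had 10 of 13 members lower and a median of -1.21 (percentile 3.74). Median scaling left 2 of 13 lower, and the deposited signals 0 lower and 1 higher with a median of 0.23. miR-92a was at -1.99 ± 0.16, miR-25 at -1.38 ± 0.15, miR-20a at -1.17 ± 0.15 and miR-19b at -0.98 ± 0.15; on the deposited signals only miR-92a of these stayed negative.

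Mesenchyme-enriched miRNAs did not stand apart from the rest. Their median was -0.59 over 8 members (percentile 65.7), with 3 lower and 1 higher. It turned to 0.85 on the deposited signals (1 lower and 4 higher) and 0.08 in the authors' table. miR-214 was lower, miR-199a-3p was at -1.25 ± 0.15, miR-199a-5p at -0.77 ± 0.16 and miR-199b* at -0.40 ± 0.16, and the last 3 turned positive on the deposited signals. The miR-125, miR-99 and miR-100 family had 3 of 6 lower and a median of -1.07 (percentile 8.1), turning to 0.36 on the deposited signals with 0 lower and 2 higher. Within it miR-99b was at -1.86 ± 0.15, miR-125a-5p at -1.46 ± 0.15, miR-125b-5p at -0.86 ± 0.17 and miR-99a at 0.79 ± 0.16; miR-125b-5p turned positive on the deposited signals.

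The miR-30 family had 2 of 6 higher (6 on the deposited signals) and a median of 0.31 (percentile 90.3), with miR-30e at 1.54 ± 0.21, miR-30a at 1.24 ± 0.16 and miR-30b at 0.23 ± 0.18. miR-30c, at -0.01 ± 0.17, was within its error of 0. The miR-15, miR-16, miR-195, miR-497 and miR-322 family had 1 higher and 1 lower of 5 (4 and 0 on the deposited signals) and a median of 0.44 (percentile 87.1). miR-15a was at 0.91 ± 0.16, miR-322 at 0.44 ± 0.16, miR-16 at -0.18 ± 0.16 and miR-15b at -1.03 ± 0.15, the last 2 positive on the deposited signals. The miR-181 family had a median of -0.23 (percentile 67.4), which turned positive with median scaling (0.29) and on the deposited signals (1.21). miR-181a was at 0.89 ± 0.19, miR-181c at 0.20 ± 0.19, miR-181d at -0.23 ± 0.17 and miR-181b at -0.72 ± 0.16; the last 2 turned positive on the deposited signals.

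**Figure D2:**
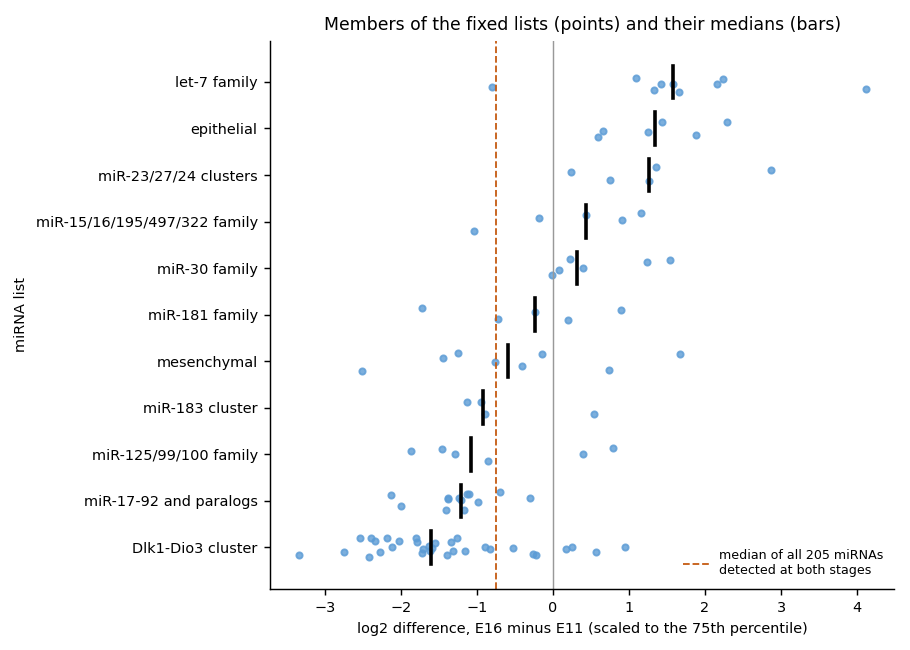
Log2 difference between E16 and E11, scaled to the 75th percentile (x axis), of the members of each list with at least 3 members detected at both stages. Points are miRNAs, black bars list medians and the dashed line the median of all 205 miRNAs (-0.74); let-7 lies highest at 1.58 and the Dlk1-Dio3 cluster lowest at -1.60, and on the deposited signals the miR-17-92, miR-125, mesenchymal, miR-181 and miR-183 medians turn positive.

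The miR-29 family was not detected at E11 or E12. Signals in this paragraph are as deposited and not scaled between arrays. miR-29a was detected at E14 (13.0 ± 3.8) and E16 (59.5 ± 7.3), and miR-29b (14.3 ± 4.4) and miR-29c (45.3 ± 6.7) at E16 alone. miR-34a was the 1 detected member of its family, at 20.5 ± 5.0, 65.5 ± 6.9 and 159.3 ± 13.0 from E12 on. miR-135a was detected at E12 alone (22.7 ± 5.1), and miR-135b at every stage with 11.6 ± 3.6, 65.2 ± 7.9, 51.6 ± 6.2 and 127.4 ± 10.8. No probe of the Hox cluster miRNAs (9 probes) or of the miR-302 and miR-290 clusters, known from pluripotent cells (22 probes), was detected on any array.

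Markers of other cell types were read beside the lists. The 8 muscle probes were not detected at any stage. The erythroid miR-451 had signals of 404, 422, 665 and 1214 at E11, E12, E14 and E16 (log2 0.15 ± 0.15 from E11 to E16, 1.59 on the deposited signals), and miR-144 was detected at E16 alone. The leukocyte miR-223 was detected from E12 and miR-142-3p at E16. Endothelial miR-126-3p was at 0.31 ± 0.15 and miR-126-5p at -0.12 ± 0.45. Cartilage miR-140 and miR-140*, also on the mesenchymal list, were at 0.73 ± 0.31 and -0.14 ± 0.20. miR-126-5p and miR-140* turned to 1.32 and 1.29 on the deposited signals. Of neural markers, miR-212 was at -0.92 ± 0.20 (0.51 on the deposited signals) and miR-128 at 0.02 ± 0.44, miR-137 was detected at E12 and E16, and miR-219 at E16. The miR-183 cluster had a median of -0.92 over 4 members (percentile 17.5), turning to 0.52 on the deposited signals, with miR-96 at 0.54 ± 0.15, miR-183 at -0.89 ± 0.15, miR-182 at -0.94 ± 0.18 and miR-183* at -1.13 ± 0.48, the last 3 positive on the deposited signals.

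No test between stages could be made. All 28 higher miRNAs, but 9 of the 77 lower, passed 2-fold under every one of the 6 scalings. This contrast follows largely from the choice of main scaling. It places the median of all miRNAs at -0.74, near the lowest of the 6 (-0.78 with all probes, 0.69 without scaling). A constant shift could lower an upward call by little, while a downward call had to outlast 1.44. Quantile normalization gave 46 higher and 44 lower, and the values of the authors' table gave 33 and 64.

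From E11 to E12 the let-7 family was already higher, with 8 of 9 members at least 2-fold up and a median of 1.19 (percentile 100). The largest differences were miR-193b (6.19-fold, 2.63 ± 0.46), let-7b (6.15-fold, 2.62 ± 0.27), miR-31 (5.04-fold, 2.33 ± 0.36), miR-152 (1.88 ± 0.44) and miR-135b (1.82 ± 0.48). Lower at E12 were miR-483 (6.40-fold, -2.68 ± 0.46), miR-323-3p (-2.10 ± 0.48), miR-466f-3p (-1.58 ± 0.53), miR-188-5p (-1.36 ± 0.19) and miR-20a* (-1.35 ± 0.42). These 10 kept their direction under all 6 scalings. Over 201 miRNAs detected at both stages, 19 were higher and 17 lower, around a median of -0.20.

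The epithelial median was 0.41 (percentile 91.7) with 0 of 6 members past 2-fold, the miR-23, miR-27 and miR-24 median 0.68 (97.9) with 1 of 5 higher, and the Dlk1-Dio3 median -0.29 (16.0) with 1 of 33 higher and 1 lower. The miR-17-92 list was at -0.55 (7.7) with 4 of 14 lower, and the mesenchymal list at 0.16 (95.5). On the deposited signals the Dlk1-Dio3 and miR-17-92 medians turned to 0.38 and 0.12, the latter with 0 of 14 lower. The epithelial median was then 1.08 with 3 of 6 higher, the miR-23, miR-27 and miR-24 median 1.35 with 4 of 5 higher, and the mesenchymal median 0.83. Detected at E12 and not at E11 were 20 miRNAs, led by miR-210 (at least 9.54-fold higher), miR-137 (6.79), miR-669a (5.75), miR-467b (5.56) and miR-31* (5.17). Detected at E11 and not at E12 were 8, led by miR-697 (at least 6.20-fold lower), miR-1906 (5.54), miR-1982* (2.39), miR-183* (1.70) and miR-134 (1.42). On the deposited signals the first 4 of these bounds are 3.90, 3.48, 1.503 and 1.07, and miR-134 has none above 1. The 5 upward bounds are 15.2, 10.8, 9.15, 8.84 and 8.21 there. The deposited signals gave 46 higher and 2 lower, and 11 higher and 2 lower held under all 6 scalings.

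Between E12 and E14 the entries furthest up were miR-2146 (10.5-fold, 3.39 ± 0.16), miR-2140 (8.59-fold, 3.10 ± 0.15), miR-494 (7.51-fold, 2.91 ± 0.16), miR-689 (7.42-fold, 2.89 ± 0.19) and miR-1187 (6.00-fold, 2.59 ± 0.43). Of these, miR-2146, miR-2140 and miR-689 have no miRNA gene in the RefSeq table. Of 27 miRNAs at least 2-fold higher at E14, 24 were at least 2-fold lower again at E16, and the other 3 were miR-31, miR-31* and miR-34a. Lower at E14 were miR-376c (5.02-fold, -2.33 ± 0.52), miR-483* (-2.03 ± 0.26), miR-369-5p (-2.03 ± 0.38), miR-411* (-1.87 ± 0.35) and miR-872 (-1.68 ± 0.51). All 10 kept their direction under the 6 scalings.

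The Dlk1-Dio3 cluster held 15 of the 32 miRNAs at least 2-fold lower at E14, with 2 of its 31 members higher and a median of -0.996 (percentile 0.01). On the deposited signals 5 were lower and the median was -0.59. The epithelial median was 0.27 (96.4), the let-7 median -0.09 (70.1; 0.32 on the deposited signals) and the mesenchymal median -0.65 (6.85). Detected at E14 and not at E12 were 37 miRNAs, led by miR-875-5p (at least 10.2-fold higher), miR-3473 (6.56), miR-671-5p (5.02), miR-1906 (5.01) and miR-1897-3p (4.95). Detected at E12 and not at E14 were 9, led by miR-137 (at least 13.8-fold lower), miR-409-5p (8.65), miR-135a (5.31), miR-136 (4.67) and miR-467e (4.03). Over 212 miRNAs the median was -0.40. Median scaling gave 34 higher and 18 lower, and the deposited signals 36 and 9; 27 higher and 9 lower held under all 6 scalings.

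**Figure D3:**
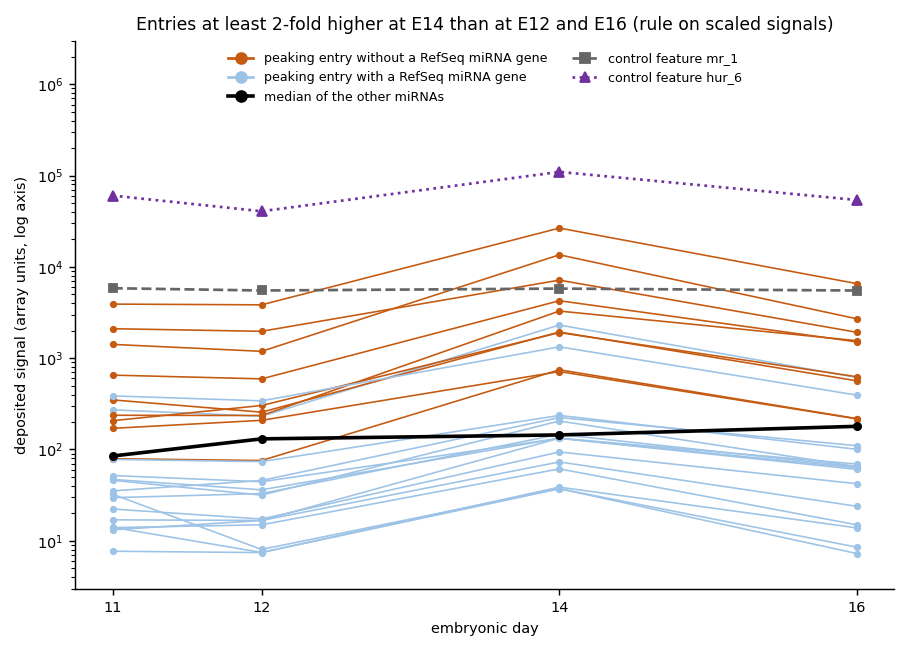
Deposited signal on a log axis (y) against embryonic day (x) for 24 entries. They were detected on all arrays and at least 2-fold higher at E14 than at both E12 and E16 after scaling. Orange lines are the 9 entries without a RefSeq miRNA gene, blue lines the other 15, black the median of the other miRNAs detected on all arrays, and grey and purple the control features mr_1 and hur_6; the entries were picked for this peak.

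From E14 to E16 epithelial miRNAs led the differences upward, with miR-203 5.34-fold higher (2.42 ± 0.16) and miR-141 4.42-fold higher (2.15 ± 0.18). They were followed by miR-29a (1.83 ± 0.45), miR-872 (1.64 ± 0.45) and miR-875-5p (1.59 ± 0.12). The epithelial list had 3 of 7 members at least 2-fold higher and 0 lower, with a median of 0.55 (percentile 97.7). Lower at E16 were miR-671-5p (8.35-fold, -3.06 ± 0.44), miR-483 (-2.72 ± 0.47), miR-2140 (-2.69 ± 0.15), miR-125a-3p (-2.49 ± 0.41) and miR-370 (-2.40 ± 0.45). These 10 kept their direction under all 6 scalings. Of 231 miRNAs detected at both stages, 17 were higher and 31 lower around a median of -0.06. Of the 31, 24 were the entries detected on all arrays that peaked at E14. miR-671-5p, undetected at E12, could not be among them.

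The let-7 median was 0.47 (percentile 99.9) with 0 of 9 members past 2-fold, the Dlk1-Dio3 median -0.23 (15.3; 0.13 on the deposited signals) and the miR-17-92 median -0.03 (45.5; 0.33 on the deposited signals). Detected at E16 and not at E14 were 19 miRNAs, led by miR-136 (at least 11.1-fold higher), miR-193 (10.7), miR-142-3p (8.84), miR-137 (6.53) and miR-29c (6.22). Detected at E14 and not at E16 were 18, led by miR-1897-3p (at least 9.61-fold lower), miR-1894-3p (7.24), miR-680 (6.55), miR-1940 (5.71) and miR-714 (5.39). Median scaling gave 30 higher and 29 lower and the deposited signals 36 and 28; 14 higher and 25 lower held under all 6 scalings.

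Over the 4 stages, 15 of the 197 miRNAs detected throughout were higher at each of the 3 steps and at least 2-fold higher at the end. They included miR-31, let-7b, let-7c, let-7d, let-7i, miR-27a, miR-22, miR-200a, miR-200c and miR-429, and 14 of the 15 held under all 6 scalings (let-7i did not). A course downward at every step with at least 2-fold in all was seen for 46, among them miR-543, miR-130b*, miR-409-3p, miR-433 and miR-214. Those 5 alone held under all scalings. Median scaling gave 27 up and 23 down, and the deposited signals 50 and 5. Without the 2-fold rule, 19 went upward and 63 downward under the main scaling, and 59 and 8 on the deposited signals. Random order of 4 values gives 4.17% each way, a share that holds only without a shift common to an array, and the direction in excess turned with the scaling.

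**Figure D4:**
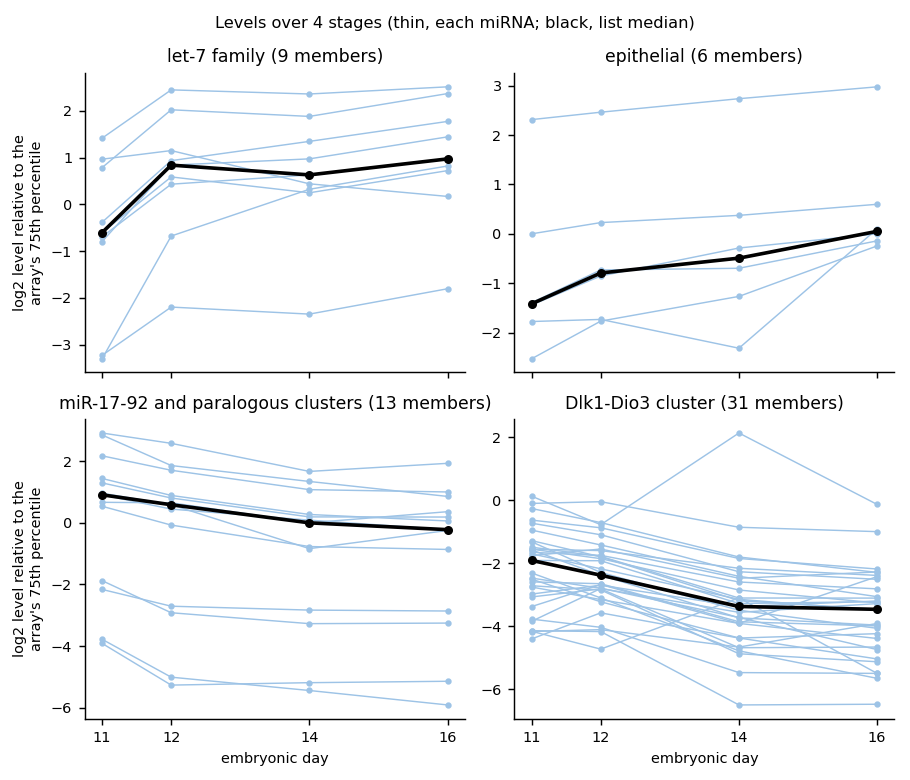
Log2 level relative to each array's 75th percentile (y) against embryonic day (x) for 4 lists, thin lines for miRNAs detected on all arrays and black for the list median. The let-7 panel steps up between E11 and E12, and the Dlk1-Dio3 panel of 31 members slopes downward to E14. On the deposited signals the miR-17-92 median turns upward from E11 to E16. The Dlk1-Dio3 median difference there is 0.38 from E11 to E12 (33 members) and -0.59 from E12 to E14.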

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

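All tests in this part were chosen after the values were seen, including those on the E14 peak and on the brightness of the arrays. The control feature hur_6 is listed because it carries a signal outside the miRNAs compared. It differed 2.698-fold between its highest and lowest array, with signals of 60407, 40693, 109779 and 53994 at E11, E12, E14 and E16. Its log2 signal at E14 lay 1.23 above the mean of E12 and E16, while the other 5 control features detected on all arrays had a median of 0.02.

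The E14 array showed the same shape in 24 entries. They were picked among miRNAs detected on all arrays for being at least 2-fold above both neighbouring stages. They held 29.8% of the summed signal at E14 and 7.41%, 5.83% and 8.67% at E11, E12 and E16. Entries undetected at E12 or E16 could not be picked. Among those, miR-671-5p was at least 5.02-fold higher at E14 than at E12 and 8.35-fold lower at E16. miR-1897-3p was detected at E14 and at neither E12 nor E16 (at least 4.95-fold up and 9.61-fold down). A brighter E14 array as a whole is argued against by the other 173 miRNAs detected on all arrays, whose median was -0.2026. Fragments of abundant longer RNAs labelled with the small RNAs may contribute: entries without a miRNA gene were 9 of 24 (37.5%) against 8 of 173 (4.62%), a gap of 32.88 points, although the idea drew on knowledge that such entries were withdrawn from the miRNA catalogue. miR-720, miR-1937b, miR-1937c and miR-1274a, also without a gene, did not peak (median 0.02), and 15 of the 24 have a gene. A difference of the E14 tooth germ itself was not tested, since that stage has 1 array.

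The deposited signals of miRNAs detected at both stages were brighter at E16 than at E11 by a median of 0.69 on the log2 scale. Brighter hybridization or scanning of the whole E16 array is argued against, for bright signals, by the 6 control features detected on all arrays. Their median difference was 0.0625, with hur_6 among them. At E11 the detected hur features had signals of 17274 or more and mr_1 had 5841, against a median detected miRNA signal of 76.6. The control miRNABrightCorner30 lay nearer to it (180), so the controls say little about dim signals. Entries with a gene record had a median of 0.72 and the 18 without one 0.62, while miR-720, miR-1937b, miR-1937c and miR-1274a had 0.10. A larger share of miRNA in the total RNA, or a better labelling, stays open, since 4 entries exclude neither.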

How the results depend on the processing

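No paired analysis was possible because each stage has 1 array. Of the alternative values of the main results, 169 stayed within the limit for a change of 1.5 times (0.58 on the log2 scale) and 60 did not; among single named miRNAs 401 stayed, 109 moved and 5 reversed. A named miRNA counts as reversed only if its sign turns and its main difference is at least 2-fold. All-probe scaling, median scaling and no scaling add a constant to all named differences and list medians of a comparison. Whether such a value stayed within 0.58 was fixed by that constant, so these values are no evidence of robustness. Signs turned for 21 of 103 named differences and 5 of 11 list medians on the deposited signals, most of them under 2-fold in the main analysis. There 95 values moved and 5 reversed while 22 stayed; quantile normalization moved 26 and left 98. The 3-fold threshold and the filter on level each moved 7 and left 1. A floor common to all arrays gave 202, 221, 244 and 248 detected miRNAs. Detection at 3 times the error could change nothing, since every detected signal already exceeds it. Without entries lacking a gene record, chosen after seeing the data, E14 versus E12 had 18 higher and E16 versus E14 had 21 lower, against 27 and 31. E16 versus E11 then had 27 higher and 69 lower. Signals close to the lowest detected values carry errors of up to 33.3%, which limits dim miRNAs.

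For E16 versus E11, higher miRNAs numbered 46 with quantile normalization, 44 with median scaling, 92 on the deposited signals, 51 with undetected values at the floor and 15 at 3-fold. Lower miRNAs numbered 44, 35 and 9 under those scalings, 41 among miRNAs above the median level and 30 at 3-fold. For E12 versus E11, higher numbered 46 on the deposited signals, 34 at the floor, 10 above the median level, 39 at 1.5-fold and 6 at 3-fold; lower numbered 26 with the 75th percentile over all probes, 2 deposited, 4 above the median level, 52 at 1.5-fold and 2 at 3-fold. For E14 versus E12, higher numbered 43 at the floor and 17 above the median level; lower numbered 20 with quantile normalization, 18 with median scaling, 9 deposited, 9 above the median level, 78 at 1.5-fold and 6 at 3-fold. For E16 versus E14, higher numbered 28 with all probes, 30 with median scaling, 36 deposited, 30 at the floor, 9 among miRNAs detected on all arrays, 6 above the median level, 37 at 1.5-fold and 5 at 3-fold; lower numbered 19 above the median level, 54 at 1.5-fold and 20 at 3-fold. Thresholds and filters change counts by construction. So do median scaling, all-probe scaling and no scaling, which differ from the main one by a constant per array. For quantile normalization, which is no constant shift, the cause was not tested.

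Courses upward numbered 27 with median scaling, 7 with steps of at least 1.2-fold, 5 without E11, 25 without E12 and 25 without E14. Courses downward numbered 27 with quantile normalization, 23 with median scaling and 25 with steps of at least 1.2-fold. Leaving out E12 or E14 leaves fewer steps to pass by construction. The drop without E11 follows from the 2-fold rule, which is then taken from E12 to E16. The steps left are among those already passed.

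On the deposited signals, an alternative for lists and named miRNAs chosen after seeing the data, list medians for E16 versus E11 were 2.781 (epithelial), 0.85 (mesenchymal), 3.016 (let-7), 0.3618 (miR-125, miR-99 and miR-100), 0.227 (miR-17-92), -0.168 (Dlk1-Dio3), 1.75 (miR-30), 1.876 (miR-15 and miR-16), 1.205 (miR-181), 2.699 (miR-23, miR-27 and miR-24) and 0.5182 (miR-183 cluster). The mesenchymal median was 0.07613 in the authors' table, and the miR-125 median -0.04831 with quantile normalization. miR-199a-3p (0.1884), miR-15b (0.4029), miR-20a (0.2624), miR-25 (0.05633) and miR-183* (0.3042) are the 5 named miRNAs at least 2-fold lower in the main analysis that turned positive on the deposited signals. Each value on the deposited signals is by construction the main value plus the 1.44 difference of the 75th percentiles.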

Other observations

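The groups in this paragraph were chosen after their values were seen, from 12 groups looked at, and signals are given as deposited. miR-221 was not detected at E11 or E12 and had signals of 40.8 ± 5.8 at E14 and 75.3 ± 8.0 at E16. Members of the miR-130 and miR-301 family parted: miR-130b (-2.22 ± 0.15) and miR-301b (-2.21 ± 0.20) were lower at E16 than at E11 under the main scaling and on the deposited signals (-0.79 and -0.78). miR-130a (-0.43 ± 0.15) and miR-301a (-0.38 ± 0.17) stood higher than both, and turned positive on the deposited signals (1.05 for miR-301a). miR-26a (0.59 ± 0.15) and miR-26b (0.44 ± 0.16) lay above the median of all miRNAs (-0.74). miR-31 and its minor arm miR-31* went the same way: miR-31 had signals of 16.2, 130, 525 and 1257 at E11, E12, E14 and E16, and miR-31* was undetected at E11 and then had 45.0, 155 and 439.

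All tests in this part were chosen after signals of many miRNAs had been seen. The criterion for the epithelial share was changed 3 times after its outcome was known. Once this was away from an outcome against the share, a gap of 4.30 from E11 against a bar of 3.86. That bar was the largest gap between neighbouring genes of the list plus 2 times its error. From E12 and E14 the gaps fell short of it (2.69 against 2.85 and 2.19 against 2.33). The epithelial list was higher at E16, with a median 2.09 above that of all miRNAs, an excess that a constant shift per array leaves as it is. Of the scalings tried, quantile normalization and the authors' table can alter it, and they gave 1.445 and 1.83, so the choice of scaling as the whole cause is argued against. A larger epithelial share of the tissue as the whole cause cannot be told apart from regulation of single genes, since 1 array per stage gives no spread between tooth germs. A share alone would move all members alike only if each were confined to the epithelium, uniform within it and read linearly. None of this was tested. From E12 to E16 the highest and lowest of 7 differed by 2.69 ± 0.32 (miR-141, miR-200b). From E14 the difference was 2.19 ± 0.22 (miR-203, miR-200b). From E11 it was 4.298, with undetected miR-141 set to the lowest detected signal there, a nominal bound. These gaps exceed their technical errors, which are no spread between samples, so they do not decide for or against the share.

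Neighbouring miRNA genes, within 10 kb, may share their change from E11 to E16. miRNAs matched to several genes were left out of all pairs. Over 181 pairs the median gap between their differences was 0.88, against 1.31 for pairs on different chromosomes, a ratio of 0.672. Shuffled differences gave 0.756 to 1.24. The shuffles were not matched on signal level, so a change that goes with level was not separated. The 44 pairs with neither member on the Dlk1-Dio3 list gave 0.440, against 0.631 to 1.43 for shuffles among the miRNAs off that list. Near-identical members of a cluster can share probe signal, so part of this may come from cross-hybridization, which was not tested. For both arms of a precursor the ratio was 0.671 over 17 pairs, within the shuffled range of 0.527 to 1.51. The 12 pairs off the Dlk1-Dio3 list gave 0.470, within 0.428 to 1.66, so a shared change of the arms could not be told from chance in either set.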
